A study of Mus musculus with 6 samples.

How the data were processed

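Total RNA was measured on Affymetrix Mouse Gene ST arrays in cultured neonatal mouse cardiomyocytes held in hypoxia. There were 6 samples, 3 with fibroblast growth factor 21 (FGF21) and 3 without, and their titles call them biological replicates 1 to 3 of each group. The labels do not say whether the replicates came from separate litters, pools of hearts or cultures, so the p-values measure the spread between these samples, which may be partly technical. Group and replicate number were taken from the sample titles.

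The deposited values are on the log2 scale and were made by the authors with the robust multi-array average (RMA), using R 3.2.2 and the affy package, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises probes. It can hide a shift common to all genes, and it compresses differences of dim genes. The chip definition and the genome build are not given in the sources used here, so no coordinates are given. The value table had 41345 rows and 6 columns, each matched to a sample. Values ran from 3.23 to 13.7, and the medians of the arrays from 5.76 to 5.83. The 3 FGF21 arrays had lower medians (5.76 to 5.79) than the 3 controls (5.81 to 5.83), so a small shift of the distributions goes with the group. The number of arrays limits the precision. None of the array pairs held identical values (0 pairs).

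Rows were named through the platform annotation. 23521 rows had 1 gene symbol, 1814 had several and 16010 are not in the naming table. Gene numbers were looked up in the RefSeq table of assembly GRCm38.p6 for names only. It held 23328 of them, and 0 symbols changed. Rows with several symbols were not named. For the 1082 genes with more than 1 row, the row with the highest mean over all 6 arrays was used, which left 22180 genes.

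The comparison was with FGF21 minus without, fitted on the 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, no covariate, two-sided). P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Differences are on the log2 scale, followed by the standard error (SE), and intervals of folds are at 95%. For gene lists, 34 lists with 673 different symbols were written before the data were examined, and 610 of these symbols had a row. Lists with at least 5 measured members, 32 in all, were tested with limma's camera at its preset correlation of 0.01, adjusted over the 32 lists. Each member was also adjusted over the list alone. In the text, "rose" and "fell" are used of genes past 0.05 when adjusted over the list alone, and of lists past camera. The erythroid and sex-linked lists had too few members for camera.

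The lists cover the FGF receptor axis, immediate targets of ERK and FGF signalling, HIF targets, glycolysis, fatty acid oxidation, oxidative phosphorylation, the TCA cycle, mitochondrial biogenesis, autophagy, antioxidant genes, apoptosis in both directions, endoplasmic reticulum (ER) stress, heat shock, fetal and hypertrophy genes, the sarcomere, calcium handling, interferon, inflammatory and TGF-beta genes, sterol synthesis, lipogenesis, cytosolic ribosomal proteins, the proteasome, p53 targets and the cell cycle. Markers of fibroblasts, smooth muscle, endothelium, leukocytes, red cells, epicardium and Schwann cells stood for other cells of the heart.

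The rule for named genes was also written before the data were examined. It takes genes past the threshold, filled up to 24 with those of smallest p among genes with a fold of at least 1.3 and groups that do not overlap, leaving out predicted genes, receptors of smell and small RNAs. It adds up to 4 genes per list of smallest p, and always Fgfr1, Klb and Fgf21. Of the genes the lists add, those named in the text are a part picked after their values were seen. So are list members beyond those 4, among them Sqle, Hmgcs1, Insig1, Lss, Srebf2, Mvd, Acaca, Robo4, Pecam1, Emcn, Dnajb9, and Birc5 and Sesn2 where they stand for the cell cycle and ER stress lists.

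Alternatives written before the data were examined were the replicate number as a block, leaving out each array in turn, all rows, 2 filters on dim genes, the mean of all rows of a gene, quantile normalization applied again, median centring, a prior with a trend and robust fit, array weights, an ordinary equal-variance statistic, other thresholds, camera with an estimated correlation, and fry. Brightness was checked with 10000 random lists of the same size, drawn from 20 bins of mean level.

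The fit was tested on simulated data for the comparison with FGF21 minus without, with 22180 genes and 3 arrays per group. Of 100 genes given a log2 change of 0.5, 82% were recovered by limma, and of 100 given a change of 1, 100%. Recovery depends on how many genes change, so these shares need not hold for the real data. There, Cyp51, at 1.09, was not called (limma adjusted p of 0.0507). 11 of 193 calls were false. A list shifted by 0.3 came out of camera with an adjusted p of 1.02e-20, and 0 of the 31 other lists passed. The simulated noise had variances drawn from the prior that limma fitted and was independent between genes, so this says nothing on lists whose genes vary together.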

Results

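Gene expression was measured in cardiomyocytes grown from the hearts of 1-day-old C57BL/6 mice. The cells were enriched by a short pre-plating step, which lets faster-attaching cells settle first, and then kept for 12 h under low oxygen, at 2% O2 with 93% nitrogen and 5% carbon dioxide. FGF21, a hormone of the fibroblast growth factor family, was added at 1 µg/ml to 3 samples and left out of 3 control samples. Each sample was hybridised to 1 array. The series was made to find genes that FGF21 regulates in hypoxic cardiomyocytes. Both groups were hypoxic, so the effect of hypoxia itself was not analysed here. Correlations between arrays over all genes ran from 0.993 to 0.997, and the first principal component, with 35.0% of the variance, had the 3 FGF21 arrays at 1.64, 13.8 and 9.49 and the controls at -13.3, -2.04 and -9.64.

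Of the 24 named genes in the comparison of FGF21 with control, 8 encode enzymes of lipid synthesis, all with higher values under FGF21. Cyp51, the lanosterol demethylase of cholesterol synthesis (probe set 17445308), stood at 8.76 ± 0.223 (SD, n = 3) with FGF21 and 7.67 ± 0.144 without, a 2.13-fold difference (95% interval 1.78 to 2.54). Fads2, a fatty acid desaturase, was 1.64-fold higher, with a log2 difference of 0.71 ± 0.08 (SE). Of the other sterol enzymes, Msmo1 was 1.97-fold, Fdps 1.89-fold, Nsdhl 1.77-fold and Fdft1 1.74-fold higher. Tfrc, the transferrin receptor that takes up iron, was 1.58-fold higher. None of these passed over all genes: the smallest adjusted p of limma was 0.0507, for Cyp51 and Fads2, and it was 0.0685 for Msmo1, Fdps, Nsdhl, Fdft1, Tfrc and Scd1 and 0.0845 for Elovl6.

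Over all 22180 genes, limma called 0 at an adjusted p under 0.05. At an adjusted p under 0.1 it gave 28 genes, 19 higher and 9 lower with FGF21, but that count was 16 without FGF21 replicate 1, 2 without FGF21 replicate 3, and 0 without FGF21 replicate 2 or any 1 of the 3 controls. An unadjusted p under 0.05 was reached by 2594 genes, against 1109 by chance, of which 1461 were higher and 1133 lower (56.3% higher, and 70.3% after median centring of each array), and by 1710 without FGF21 replicate 2. With quantile normalization applied again it was reached by 2119 genes, 51.3% of them higher. Groups did not overlap for 17.1% of genes, where chance gives 10%. The count of 0 depends on the setting: with genes below the median level left out limma called 58, with a trend and robust prior 16, and with an ordinary equal-variance statistic 0. Without FGF21 replicate 1 it called 2, Cyp51 and Cenpq, the second of which falls outside the rule for named genes.

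The other genes among the 24 named were spread over several functions. Their groups do not overlap because the rule for named genes requires it. Higher with FGF21 were Nmrk2, a nicotinamide riboside kinase of muscle, by 0.50 ± 0.07 on the log2 scale (SE), the nucleoside transporter Slc28a2 by 0.59, Dnajc15 by 0.52, Myl6 by 0.54 and Rai14 by 0.41. H2-Q10 was higher by 0.57, but its other row differed by -0.00016, and the family has near-identical members, so its value is uncertain. Lower were Kcnj8, a pore subunit of ATP-sensitive potassium channels, at -0.65 ± 0.09 (1.57-fold lower), the matricellular gene Sparcl1 at -0.63, the co-stimulatory receptor Tnfrsf9 at -0.55, the Wnt inhibitor Wif1 at -0.47 and Isoc2a at -0.43. Derl3 and Ero1b, which act in degradation and in disulfide formation in the ER, had differences of -0.70 and -0.51. Fthl17e and Psg-ps1, members of gene families with close copies, had differences of -0.50 each and are uncertain for that reason. Adjusted p-values of limma for these genes lay between 0.0685 and 0.0862. Some were dim: means without FGF21 were 5.06 for Slc28a2, 5.754 for Myl6, 5.03 for Fthl17e and 5.73 for Psg-ps1, below the lowest array median of 5.765.

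Genes of sterol synthesis rose together. All 13 measured members, of 18 written, were higher with FGF21, with a median log2 difference of 0.80 (1.74-fold) and quartiles of 0.54 and 0.85. Adjusted over the list alone, 12 rose, and over all genes 0 passed. Nsdhl is not on the list. Besides Cyp51, Msmo1, Fdps and Fdft1, Sqle, the squalene monooxygenase, rose by 0.85 ± 0.14 (SE), Hmgcs1, the HMG-CoA synthase, by 0.75 ± 0.14, Lss by 0.80 ± 0.16, and Insig1, which holds back SREBP processing, by 0.80 ± 0.17. Srebf2, which encodes the transcription factor of these genes, rose by 0.36 ± 0.08. Mvd was the exception, at 0.09 ± 0.08 (0.0156 without FGF21 replicate 2 and 0.150 without FGF21 replicate 3). The list mean was 8.66, 8.29 and 8.19 in the FGF21 arrays and 7.61, 7.68 and 7.74 in the controls. Camera gave the list an adjusted p of 1.59e-20, and an adjusted p = 0.312 with an estimated correlation, because its genes varied together (estimated correlation 0.705).

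**Figure D1:**
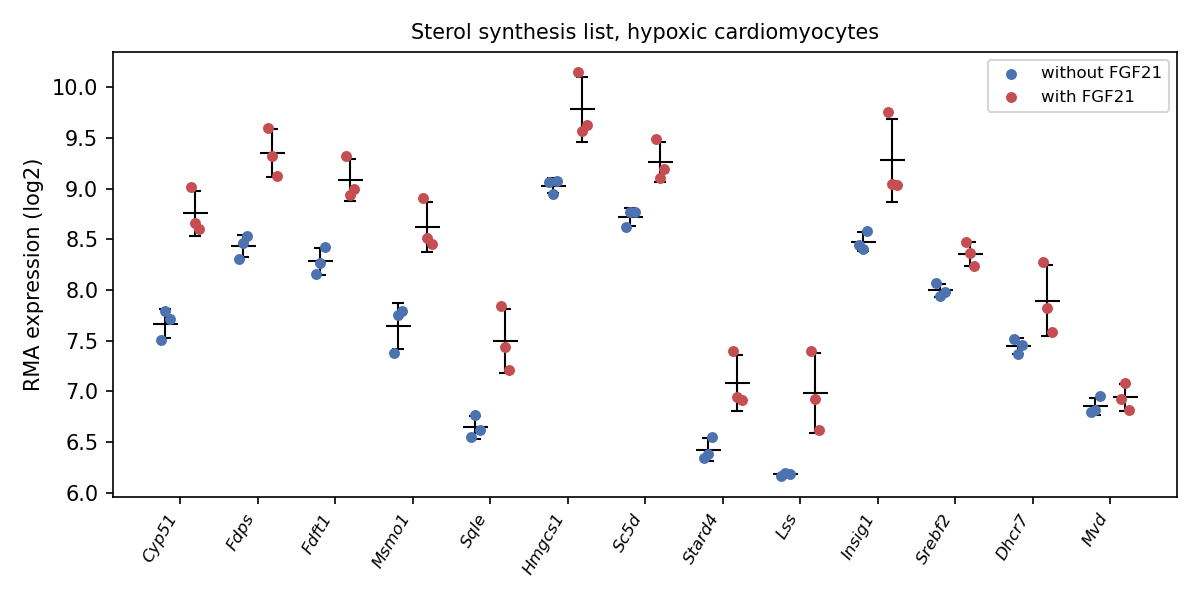
RMA expression (log2) of the 13 measured genes of the sterol synthesis list, with 1 point per array, 3 arrays without FGF21 (blue) and 3 with it (red), and black bars for mean and SD. The groups do not overlap for 12 genes, Cyp51 with means of 7.67 and 8.76 among them, and overlap for Mvd.

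Of 15 lipogenesis genes, 10 were higher and 5 lower with FGF21. Camera gave the list an adjusted p of 0.0033, and an adjusted p = 0.446 with an estimated correlation. Adjusted over the list alone, 5 of 15 members rose: Elovl6, a fatty acid elongase, by 0.88 ± 0.14 (SE, 1.83-fold), Acly, the ATP citrate lyase, by 0.61 ± 0.12, Fasn, the fatty acid synthase, by 0.61 ± 0.13, Scd1, the stearoyl-CoA desaturase, by 0.54 ± 0.08, and Acaca, the acetyl-CoA carboxylase, by 0.34 ± 0.08. The 10 others did not pass, and the median difference was only 0.09, against a mean of 0.20. The median was 0.0585 without FGF21 replicate 1 and 0.0377 without FGF21 replicate 2. Genes of fatty acid oxidation did not pass, with a median of -0.03 over 25 members and a camera adjusted p of 0.375. The median ran from -0.0398 without control replicate 2 to -0.00838 without control replicate 1. With quantile normalization applied again, their median was -0.08 and camera's adjusted p 0.0215.

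Cell cycle genes rose as a list by less. Of 26 members, 23 were higher, with a median of 0.17 (1.13-fold), and the list mean was 7.78 ± 0.0307 (SD) with FGF21 and 7.62 ± 0.0529 without. Adjusted over the list alone, 4 rose: the cyclin gene Ccnd1 by 0.46 ± 0.09 (SE), the replication helicase gene Mcm4 by 0.33 ± 0.08, the spindle motor gene Kif11 by 0.30 ± 0.08 and Birc5 by 0.28 ± 0.08. Ccne1, another cyclin gene, fell by 0.28 on the log2 scale. Camera gave an adjusted p of 1.72e-08, and an adjusted p = 0.313 with an estimated correlation. The 5 genes became 2 without FGF21 replicate 3, 3 without control replicate 1 and 9 without control replicate 2.

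In the reported setting, endothelial markers were the only one of the 32 tested lists to fall. With quantile normalization applied again, the fatty acid oxidation, ER stress and calcium handling lists fell too. Values here are of the endothelial list in the reported setting. Of 15 members, 13 were lower with FGF21, with a median of -0.22, and the list mean was 7.29 ± 0.0963 (SD) against 7.51 ± 0.0931 in controls. Adjusted over the list alone, 7 fell, among them Kdr, the VEGF receptor gene, at -0.61 ± 0.17 (SE), Cdh5, the endothelial cadherin gene, at -0.44 ± 0.13, the transcription factor gene Erg at -0.35 ± 0.08, Esam at -0.33, Pecam1 at -0.32, Robo4 at -0.29 and Emcn at -0.27. Camera gave an adjusted p of 1.43e-05, and an adjusted p = 0.446 with an estimated correlation. The 7 genes became 0 without FGF21 replicate 1, without control replicate 1 and without control replicate 2, and the median weakened to -0.137 without FGF21 replicate 1. Kdr was at -0.41 without control replicate 1, and Pecam1 at -0.21 without FGF21 replicate 1.

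**Figure D2:**
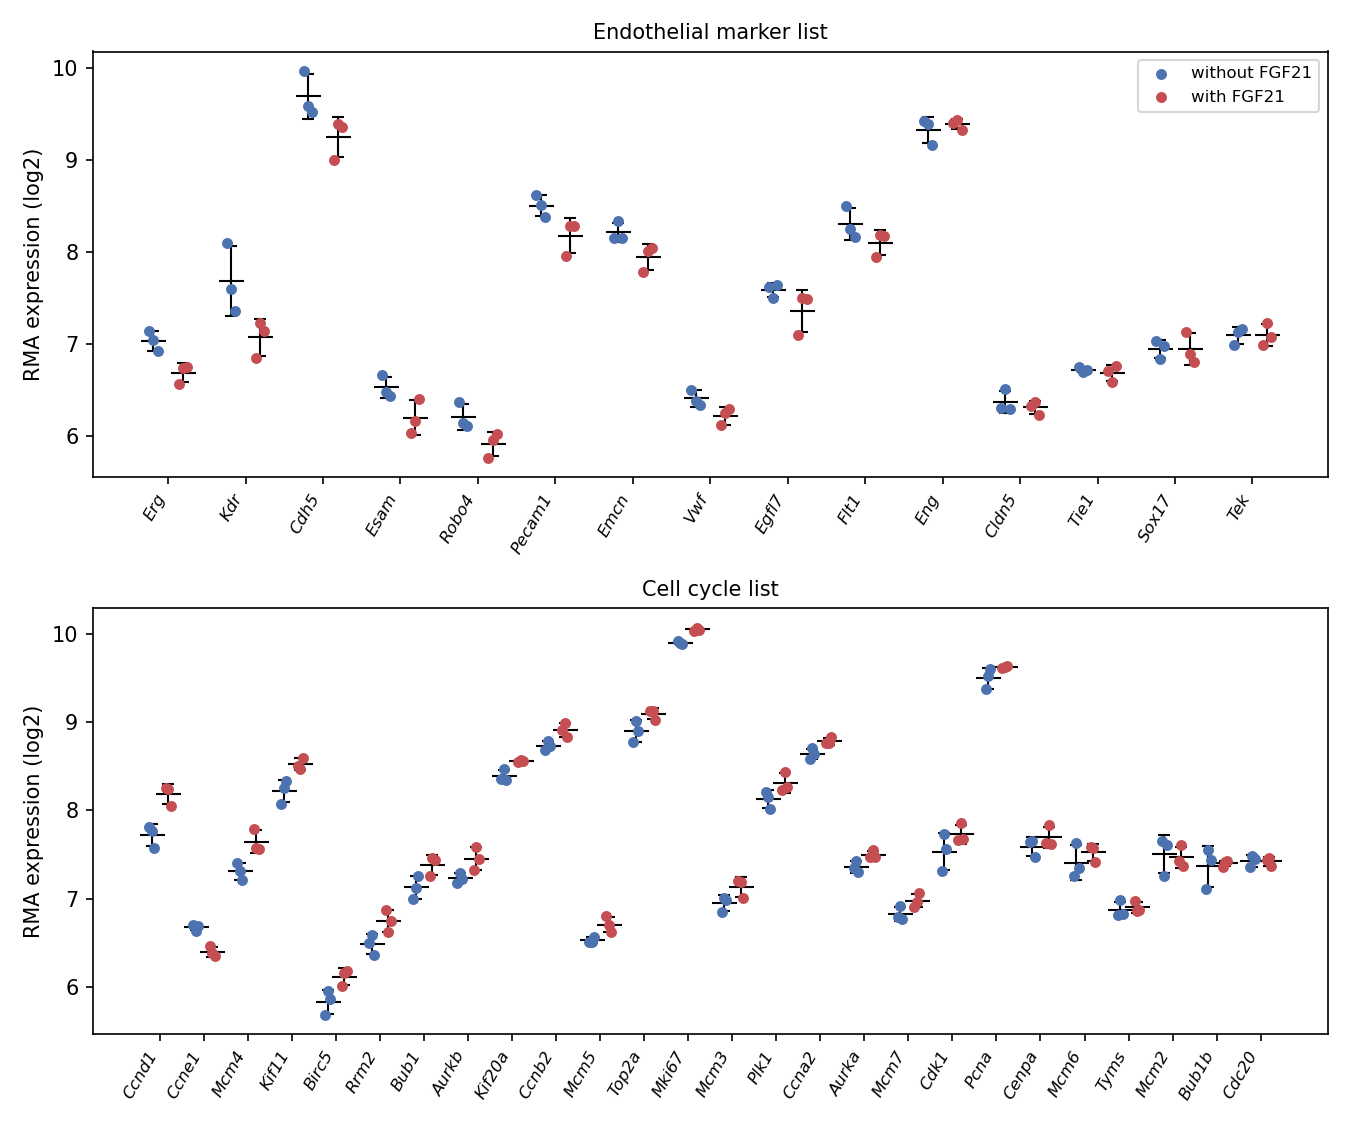
RMA expression (log2) of genes of the endothelial and cell cycle lists, with 1 point per array for the 3 arrays without FGF21 and the 3 with it, and black bars for mean and SD. Kdr means are 7.69 without and 7.07 with FGF21, and Ccnd1 means are 7.72 and 8.18.

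Markers of other cells of the heart moved less. The epicardial and mesothelial list had a median of 0.09 over 10 members, with the keratin gene Krt19 up by 0.31 ± 0.08 (SE) when adjusted over the list alone; camera gave an adjusted p of 0.0362, and an adjusted p = 0.606 with an estimated correlation. The epicardial call was lost without FGF21 replicate 2 (median 0.0653), control replicate 1 (0.0352) or control replicate 2 (0.125). Medians of the lists that did not pass were -0.00 for fibroblasts, 0.02 for smooth muscle, -0.05 for leukocytes and -0.15 for Schwann and neural markers, of which S100b fell by 0.22 adjusted over the list alone and Tubb3, at 0.47 (0.26 without FGF21 replicate 1), did not pass. The mean of the Schwann and neural list was -0.01, and its median -0.0919 without FGF21 replicate 2. Of 3 red cell markers, Epb42 fell by 0.21 adjusted over the list alone. Epb42 and S100b were dim, with means without FGF21 of 5.53 and 5.56, below the lowest array median of 5.76. Their limma adjusted p-values over all genes were 0.281 and 0.250. The cardiomyocyte lists did not pass: sarcomere genes had a median of -0.01 over 23 members, with camera's adjusted p at 0.763, and calcium handling genes -0.05 over 19, with 0.219 (median from -0.0960 without control replicate 2 to -0.0319 without control replicate 1). With quantile normalization applied again, the calcium handling list passed camera, at a median of -0.10 and an adjusted p of 0.018. Within the sarcomere list Csrp3, a muscle LIM protein gene, rose by 0.30 ± 0.06 adjusted over the list alone. The sex-linked genes differed by 0.19 for Uty, 0.16 for Kdm5d, 0.07 for Eif2s3y and -0.11 for Xist, none past limma's adjustment over the list alone. Each moved by over 1.5 times with an array left out: Uty to 0.0896 without FGF21 replicate 3, Kdm5d to 0.0755 without FGF21 replicate 2 and 0.251 without FGF21 replicate 1, Xist to -0.0638 without FGF21 replicate 1 and Eif2s3y to -0.0445 without control replicate 1.

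Of the remaining lists that rose, each moved by little. Heat shock genes had a median of 0.11, with 12 of 13 higher and the chaperone gene Hsph1 up by 0.35 ± 0.09 (SE) adjusted over the list alone; camera gave an adjusted p of 0.000704, and an adjusted p = 0.312 with an estimated correlation. The p53 targets had a median of 0.07, a camera adjusted p of 0.00411, and an adjusted p = 0.312 with an estimated correlation. Cytosolic ribosomal proteins had a median of 0.09 (camera adjusted p of 0.0116, and an adjusted p = 0.761 with an estimated correlation), and the proteasome 0.06 (camera adjusted p of 0.0264, and an adjusted p = 0.761 with an estimated correlation). No member of the p53, ribosomal and proteasome lists passed limma adjusted over the list alone. The ribosomal call was lost without FGF21 replicate 1 (median 0.0727) or control replicate 1 (0.0312), and the proteasome call without FGF21 replicate 2 (0.0467) or control replicate 1 (0.0359). The p53 median was 0.116 without control replicate 2. Brighter genes were shifted upwards in general: the median difference was 0.05 in the brightest of 5 equal bins of genes and -0.05 in the next-to-dimmest. Of random lists of the same brightness, 69.2% had a less extreme median than the proteasome list, 82.65% than the epicardial list, 88.6% than the p53 list and 97.26% than the lipogenesis list. The shares were 98.75% for heat shock and 99.95% for the ribosomal list.

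**Figure D3:**
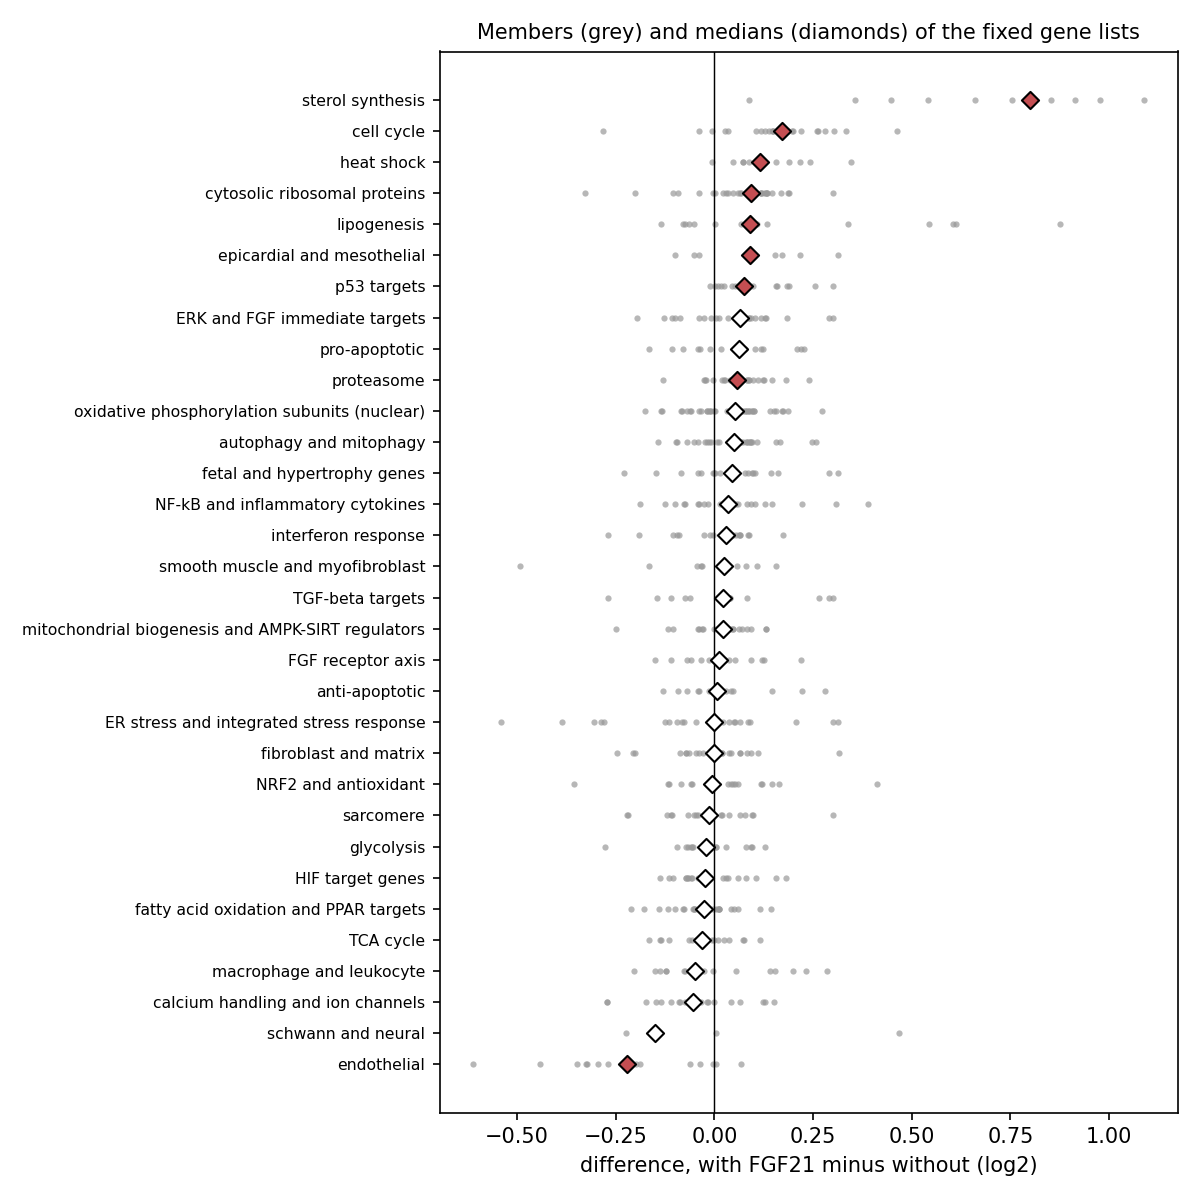
Differences with FGF21 minus without (log2) of the members (grey) and medians (diamonds, red where camera's adjusted p with the preset correlation is under 0.05) of the 32 tested gene lists. The sterol synthesis median of 0.80 stands apart, and the endothelial median of -0.22 is the only red one below 0.

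Stress genes of the ER went both ways. The ER stress list had a median of -0.00 over 23 members, and camera gave an adjusted p of 0.298. The median ran from -0.0541 without control replicate 1 to 0.00835 without control replicate 2. Adjusted over the list alone, 4 fell: Creld2, by 0.54 on the log2 scale, Dnajb9, by 0.39, Hspa5, which encodes the chaperone BiP, by 0.31, and Sdf2l1, by 0.28. On the same criterion 2 rose: Psat1, an enzyme of serine synthesis, by 0.31 ± 0.09 (SE), and Sesn2 by 0.30 ± 0.10, which was 0.18 without FGF21 replicate 2. With quantile normalization applied again, the list passed camera with a median of -0.07 and an adjusted p of 0.00469, and it passed with genes below the median level left out as well.

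The receptor axis of FGF21 did not differ measurably. Fgfr1, its main receptor, stood at 8.68 ± 0.134 (SD, n = 3) with FGF21 and 8.64 ± 0.0489 without. Klb, the co-receptor beta-Klotho, was at 5.13 ± 0.187 and 5.19 ± 0.0836, and Fgf21 itself at 5.84 ± 0.0422 and 5.86 ± 0.218. In the order of genes by mean level, dimmest first, Fgfr1 stood at 89.5%, Fgf21 at 41.5% and Klb at 25.1%. Whether Klb was above background was not tested, so its lack of a difference says little. Of the 14 axis genes, 0 passed limma over all genes or adjusted over the list alone, and 2 had an unadjusted p under 0.05. Among the immediate targets of ERK and FGF signalling, Jun rose by 0.30 ± 0.07 (SE) adjusted over the list alone; the list had a median of 0.06, or 0.0250 without control replicate 3, and a camera adjusted p of 0.219.

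Lists of hypoxia, energy metabolism and cell death did not pass camera. HIF targets had a median of -0.02 (adjusted p of 0.763), glycolysis -0.02 (0.763), the TCA cycle -0.03 (0.491), oxidative phosphorylation 0.05 (0.182), mitochondrial biogenesis 0.02 (0.763) and autophagy 0.05 (0.219). Oxidative phosphorylation passed camera without control replicate 3, at a median of 0.0767 and an adjusted p of 0.0315, and had a median of 0.0214 without control replicate 1. The TCA cycle median was -0.00575 without FGF21 replicate 2. Pro-apoptotic genes had a median of 0.06 (0.182), anti-apoptotic genes 0.01 (0.678) and antioxidant genes -0.01 (0.802). Fetal and hypertrophy genes had a median of 0.05 (0.232); of these, the natriuretic peptide gene Nppb rose by 0.31 ± 0.08 (SE), Ccn2 rose by 0.29 ± 0.07 (0.15 as the mean of its rows) and Fhl2 fell by 0.23, adjusted over the list alone. Inflammatory genes had a median of 0.03 (0.304), with the cyclooxygenase gene Ptgs2 up by 0.31 ± 0.07 adjusted over the list alone, TGF-beta targets 0.02 (0.678) and interferon genes 0.03 (0.950). Without control replicate 3, the median was 0.0168 for fetal and hypertrophy genes and 0.00906 for inflammatory genes. The mean and camera's direction opposed the median for the antioxidant and interferon lists, and the mean alone opposed it for smooth muscle.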

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

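Counts of list members past the adjustment over the list alone were added as a result after the data were seen; all other alternatives were set before. The count was 12 for sterol synthesis and 5 for lipogenesis in each of the 10 settings run, and camera's calls for the sterol, endothelial, cell cycle, heat shock and lipogenesis lists held in 10 of the 12 settings run for lists, the exceptions being the estimated correlation and fry. None of the 24 named genes changed sign. Their groups do not overlap by the rule that chose them, so leaving out an array could not turn a sign. Whether the replicate numbers pair the arrays stays open. Deviations of same-numbered arrays correlated at 0.103, 0.158 and 0.00653, against -0.160 to 0.0416 for differently numbered arrays. By this measure 4 of 6 arrays were closest to their own number. A replicate block raised the genes at a limma adjusted p under 0.1 from 28 to 46. Those at an unadjusted p under 0.05 went from 2594 to 2902. With the replicate block limma called 0 genes, as without it, 8 cell cycle members passed, and 1 other cell type list did, the epicardial list (median 0.0893) having an adjusted p of 0.0628; camera's direction for smooth muscle (0.0234) turned.

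Genes called by limma, 0 in the reported setting, were 58 with genes below the median level left out and 26 with the dimmest 25% left out, where fewer genes are tested. They were 2 with the mean of all rows, 5 with quantile normalization again, 2 with median centring, 16 with a trend and robust prior, 2 with array weights, and 28 at both looser thresholds (adjusted p under 0.1, and unadjusted p under 0.05 with a fold of at least 1.5); the cause was not tested. Leaving out single arrays gave 0 to 2.

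With an estimated correlation, camera called 0 lists and 0 of other cell types. Adjusted p-values became 0.312 for sterol synthesis (median 0.801), heat shock (0.115) and p53 targets (0.0744), 0.313 for the cell cycle (0.171), 0.446 for the endothelial (-0.222) and lipogenesis (0.0902) lists, 0.606 for the epicardial list (0.0893) and 0.761 for ribosomal proteins (0.0936) and the proteasome (0.0582). Fry, which does not compare a list with other genes, called 1 list, p53 targets, and 0 of other cell types. Its adjusted p-values were 0.0852 for sterol synthesis, 0.0931 for the cell cycle, 0.0790 for heat shock, 0.230 for the endothelial list, 0.170 for lipogenesis, 0.344 for the epicardial list, 0.473 for ribosomal proteins and 0.393 for the proteasome.

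With genes below the median left out, 1 other cell type list passed, and the calls ended for the epicardial (0.0893), ribosomal (0.0986), proteasome (0.0699) and p53 (0.0744) lists. Camera's direction turned there, with the sign of the median only for the anti-apoptotic list, for mitochondrial biogenesis (0.0221), antioxidant (-0.00995), anti-apoptotic (-0.0132), smooth muscle (0.0298) and TGF-beta (0.0223) lists. With the mean of all rows the epicardial (0.0893) and ribosomal (0.0682) calls ended, leaving 1 other cell type list, and camera's direction for smooth muscle (0.0234) turned. With quantile normalization again the epicardial (0.0239), proteasome (0.0196) and p53 (0.0588) calls ended, leaving 1 other cell type list, and 3 cell cycle members passed. The sign turned there for Fgfr1 (-0.0295) and Fgf21 (0.0235), and camera's direction for mitochondrial biogenesis (-0.0161), autophagy (-0.00545), antioxidant (-0.0475), anti-apoptotic (-0.0448), smooth muscle (-0.0123) and TGF-beta (-0.0449), with the median's sign in all but the antioxidant list.

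Leaving out single arrays gave these ranges, with changes of sign, of camera's direction or of a call: Fgfr1 -0.00775 to 0.113, Klb -0.142 to 0.0426, Fgf21 -0.130 to 0.0870, Eif2s3y -0.0445 to 0.138, endothelial members 0 to 8, cell cycle members 2 to 9, other cell type lists 1 to 2. Medians ran from -0.0317 to -0.00533 for HIF targets, -0.0648 to 0.0357 for glycolysis, -0.0541 to 0.00835 for ER stress, -0.0184 to 0.0357 for anti-apoptotic genes, -0.0147 to 0.0357 for the FGF receptor axis, 0.0214 to 0.0767 for oxidative phosphorylation, -0.0136 to 0.0612 for mitochondrial biogenesis, -0.0116 to 0.0392 for antioxidant genes, -0.0440 to 0.0245 for the sarcomere, -0.0287 to 0.0163 for fibroblasts, -0.0368 to 0.0370 for smooth muscle, -0.0969 to 0.00151 for leukocytes, -0.0220 to 0.0559 for interferon, 0.00708 to 0.0489 for TGF-beta, 0.0352 to 0.130 for the epicardial list, 0.0312 to 0.107 for ribosomal proteins and 0.0359 to 0.0854 for the proteasome. The last 3 lost their call without control replicate 1, and each also without at least 1 other array. Fatty acid oxidation, ER stress and calcium handling gained a call with quantile normalization again and with genes below the median left out, and oxidative phosphorylation without control replicate 3. The cause of these turns was not tested. Signal over background was not used here, so dim genes such as Klb have no stated floor.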

Other observations

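The follow-up lists below and the tests on brightness and on shares of other cells were chosen after the fixed lists' results were seen, and the members of the follow-up lists were not looked at before. A second list of sterol and SREBP target genes had 12 of 13 members higher with FGF21, with Slc25a1 at 0.32, Aacs at 0.35 and Pcyt2 at 0.36. A second endothelial list had 20 of 24 members lower, 9 of them past limma adjusted over the list alone, among them Gpihbp1 at -0.45, Adgrl4 at -0.45 and Cd34 at -0.32, while Ptprb was higher by 0.17 and past it as well. A second cell cycle list had 34 of 41 members higher, 13 of them past limma adjusted over the list alone, among them Hmmr at 0.38 and Ndc80 at 0.31. These genes were picked after their values were seen.

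Among 8 pericyte genes the median was -0.00 and camera's p was 0.137, while Abcc9, at -0.45, Mcam, at -0.38, and Vtn, at -0.24, were lower and past limma adjusted over the list alone. Abcc9 encodes the regulatory subunit that pairs with the channel pore of Kcnj8. In the ER, a second list of chaperone and folding genes had a median of -0.0898, with 19 of 23 lower. Camera's adjusted p over the follow-up lists was 0.00189, and 0.342 with an estimated correlation. A second list of amino acid and ATF4 target genes had a median of 0.0565, with 15 of 18 higher. Its camera adjusted p was 0.05002, and 0.443 with an estimated correlation. In both lists 0 members passed limma adjusted over the list alone. Of 17824 rows without a single symbol, limma called 0 over all rows and 1692 had an unadjusted p under 0.05. The row of smallest adjusted p, 17378310, was higher by 1.42 with an adjusted p of 0.245.

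The rise of sterol genes may be an effect of FGF21 on their common regulation, as a hypothesis. Against a shift tied to brightness, 100% of 10000 matched random lists had a less extreme median, and against a single array, the lowest median with an array left out was 0.568. A changed share of a listed cell type would need a type list with as large a rise, and the highest of those medians was 0.0893, below the lower sterol quartile of 0.54. The rise was not limited to the fixed list, since the second list had a median of 0.197 and a camera p of 4.18e-05, though p = 0.116 with an estimated correlation (adjusted p = 0.270 over the follow-up lists). LXR targets, read for a lower sterol level, had a median of -0.0326, with 5 of 7 lower, Abca1 at -0.17 and Abcg1 at -0.12 among them. Lpcat3, higher by 0.24, was the only 1 past limma adjusted over the list alone. These targets leave a lower sterol level open. The 10 splits of the arrays are too few for a share under 0.05 (1 split as large, 0.80 for the real split and 0.42 for the highest other).

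The fall of endothelial markers could come from a lower share of endothelial cells, since the second list had a median of -0.118 and a camera p of 1.89e-06. That call is lost with an estimated correlation (camera p = 0.0390, adjusted p = 0.228 over the follow-up lists). Of the second list's 24 members, 9 passed limma lower adjusted over the list alone, Ptprb passed higher and 14 did not pass. Among the 14, Plvap and Clec14a were at 0.05, Ushbp1 at 0.02, She at -0.004 and Sox7 at -0.02. Of these, Clec14a (5.51) and She (5.18) had means without FGF21 below the lowest array median of 5.76, so their flat values say little. An even loss of endothelial cells would lower brighter members too. Ptprb (8.47 without FGF21) was higher, and Plvap (6.92), Ushbp1 (6.45) and Sox7 (6.29) changed little. A lower share alone may thus not account for all of these markers. Brightness does not account for the fall, as 100% of matched lists were less extreme, but lower expression of some genes within endothelial cells stays open. So does a wider change in vessel wall cells: Abcc9, Mcam, Vtn, Kcnj8 (-0.65) and Rgs5 (-0.49, or -0.28 without FGF21 replicate 1, picked after its value was seen) were lower in value too. Abcc9 was bright, at 10.2 without FGF21, and which cells carried these transcripts was not tested. Against a wider change, the 5 other genes of the pericyte list lay between -0.02 and 0.09, and the list did not pass, with a camera p of 0.137. Vtn (5.54 without FGF21) and, among the 5 others, Higd1b (5.51) were dim, below the lowest array median. Without FGF21 replicate 1, control replicate 1 or control replicate 2, 0 fixed-list members passed limma adjusted over the list alone, and the 10 splits are too few for a share under 0.05, with 1 as large, 0.22 for the real split and 0.20 for the highest other.

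The rise of cell cycle genes may reflect more transcripts of cell division genes in general, since the second list had a median of 0.160 and a camera p of 5.76e-12, though p = 0.0651 with an estimated correlation (adjusted p = 0.228 over the follow-up lists). Brightness does not account for it, as 100% of matched lists were less extreme. Which cells carried these transcripts was not tested. The 10 splits are too few for a share under 0.05, with 1 as large, 0.17 for the real split and 0.11 for the highest other. For the whole comparison they are too few as well: all 10 splits gave 0 genes past limma's adjustment, 1 of 10 gave as many genes at an unadjusted p under 0.05 (2594 for the real split, 1994 for the highest other), and 1 of 10 as many lists past camera (9 and 8).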
